A study of Mus musculus with 14 samples.

How the data were processed

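The series holds 14 two-colour Agilent whole-genome mouse arrays of liver RNA, 5 from mice on the standard diet, 5 from mice on the high-calorie diet and 4 from mice on the high-calorie diet with resveratrol, grouped as the labels give them. Per the labels, RNA was purified on Qiagen RNeasy columns and amplified linearly, the animal's RNA carried Cy3, and the Cy5 channel of every array held a pool of 5 standard-diet livers. There was no dye swap, so a probe's dye effect is shared by all arrays and cancels in differences between groups. The labels call the animals replicates and do not say that equal replicate numbers pair them.

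Per the file headers, the deposited scanner files hold the intensity of each spot and of its local background in both channels, from Agilent Feature Extraction 7.5.1, with background-subtracted and dye-normalised processed signals in intensity units beside them. The authors also deposited a value table whose unit is a score. Each of its columns has a mean of 0 and an SD of 1, with column medians from -0.0497 to 0.00234, and follows the log of the animal's processed Cy3 signal with a correlation of 0.983 to 0.985. How those scores were made is not given in the sources used here. Their log base cannot be read from them, and higher scores mean more RNA in the animal.

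Each array has 43790 spots, of which 2256 are controls, and 41174 distinct probes. Probes were matched to the RefSeq gene table of assembly GRCm38.p6 by the systematic name (11450 probes), the accession list (6962), the gene name (1502) or an older gene name (938). In this way 20852 probes were matched to 1 gene each, giving 15940 genes, and 20322 probes stayed unmatched and were tested under the names the files give. No coordinates were used.

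Spot mean signals were corrected with the normexp method and an offset of 50, log2 ratios of animal to pool were normalised by loess within each array with control spots at weight 0, and 576 spots with the scanner's outlier flag were left out. Spots of one probe were averaged, and each gene was represented by its brightest probe over all arrays. Genes well above background in Cy3 on at least 4 arrays were kept, which left 32675 of 36096 genes. A linear model with the 3 groups was fitted in limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with empirical Bayes variances and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05, and rose, fell and passed refer to these calls.

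For gene groups, 35 lists with at least 5 tested genes each were fixed by hand and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within each comparison. Counts adjusted over the list alone apply the same limma p-values with the adjustment confined to the list's genes. Alternatives were camera with an estimated correlation, fry, and an exact permutation of the list mean over the arrays. Whether the effects of resveratrol and diet oppose each other was measured as the correlation across genes between both log2 differences, with the high-calorie arrays divided so that no array entered both, as the median over 20 divisions. Its test was a two-sided exact permutation over all relabellings of the high-calorie and resveratrol arrays.

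The genes named were, per comparison, the 8 largest rises and the 8 largest falls among genes with a matched symbol that passed and whose groups did not overlap on any array. Within each list up to 4 passing members with the smallest adjusted p were eligible, or up to 2 given as values where none passed. Sirt1, Ppargc1a, Igf1, Igfbp1, Scd1, Srebf1, Fasn, Cpt1a, Pparg, Cyp1a1, Cyp7a1 and G6pc were named whatever their result. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives for batches, array brightness, a smaller offset, the joint omission of 2 arrays and the exact permutation of list means were chosen after seeing the data.

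Alternatives covered background correction, the scanner's processed signals, median centring in place of loess, quantile normalisation of the average intensities, the Cy3 channel alone, the deposited scores, filters on dim probes, the handling of several probes per gene, array weights, a replicate block and leaving out each array. Extraction days and slide numbers were read from the deposited files and labels. The slide number series were made here by cutting the sorted numbers at their largest gap. The extraction day is the day on which Feature Extraction processed the array image, not a day of RNA purification. Each slide carried 1 array and no scan date was usable, so a slide or scan-date block was not run.

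The linear model and its calls were tested on simulated log2 ratios with 200 of 32675 genes changed. The noise was independent between genes, with no batch or outlying array. The steps before the model, from background correction to the filter, were not tested. At a log2 change of 0.5, 1 and 2 the share recovered was 83.6%, 97.0% and 100% for high-calorie against standard diet, 80.6%, 97.0% and 100% for resveratrol against high-calorie, and 82.1%, 95.5% and 100% for resveratrol against standard diet. Of 199, 189 and 192 calls, 12, 4 and 7 were false. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for gene matching and plots. The number of arrays limits the precision of every value.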

Results

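Liver RNA from 14 male C57BL/6 mice aged 1 year was measured on Agilent whole-genome mouse arrays, 1 animal per array. The standard diet (AIN-93G) was fed to 5 mice, a high-calorie form of it with 60% of calories from fat to 5 mice, and the high-calorie diet with 0.04% resveratrol, a plant polyphenol, to 4 mice. These 3 groups are called standard-diet, high-calorie and resveratrol mice here. Each array compared the animal's RNA in the Cy3 dye with a reference pool of standard-diet livers in the Cy5 dye, so every value is a log2 ratio of animal to pool. The share of probes well above background in the Cy3 channel was 77.8% to 88.2% in standard-diet, 83.5% to 91.8% in high-calorie and 81.9% to 92.4% in resveratrol mice. The median net Cy3 signal was 66.0 ± 13.6 (SD, n = 5), 84.4 ± 20.8 (SD, n = 5) and 79.4 ± 15.9 (SD, n = 4) intensity units in that order, so the high-calorie arrays were on average the brightest.

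After filtering, 32675 genes were tested, of which 15232 had a matched symbol. The first principal component of the log2 ratios held 33.8% of the variance. It lay between -26.1 and 3.77 in standard-diet mice (mean -14.1, n = 5), between 14.7 and 22.1 in high-calorie mice (mean 18.3, n = 5) and between -18.9 and 3.95 in resveratrol mice (mean -5.25, n = 4). The value of 3.77 belonged to standard-diet replicate 5 and that of -18.9 to resveratrol replicate 3. The comparisons asked what the high-calorie diet changed in the liver, what resveratrol changed on that diet, and how far the resveratrol mice still differed from mice on the standard diet.

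The high-calorie diet raised many genes of fat storage, fatty acid oxidation, drug metabolism and the interferon response in the liver, and it lowered most of the genes tested that male mice express more than females. Of 17 genes that females express more than males 8 rose. Camera called 14 of the 35 lists at its preset correlation and 2 with an estimated correlation, which were lipid droplets with PPAR-gamma targets and male-biased genes. The largest rise was in Cidea, a lipid droplet protein gene, with a log2 difference of 4.11 ± 0.56 (SE), which is 17.3-fold (adjusted p = 0.000683). The largest fall was in Hsd3b5, a male-biased steroid dehydrogenase gene, with a log2 difference of -4.19 ± 0.33 (SE) and an adjusted p of 1.68e-05. Of the 32675 genes, 3084 differed between high-calorie and standard-diet mice, 1755 higher and 1329 lower, and 107 of them differed by more than 2-fold.

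Fat storage genes stood out among the largest rises. Cd36, which takes up fatty acids, rose by 2.26 ± 0.18 (SE, log2) and Cidec, a lipid droplet protein gene, by 2.12 ± 0.18. Cfd, the complement factor adipsin made mostly by fat cells, rose by 2.52 ± 0.31. Of the 14 tested genes of lipid droplets and PPAR-gamma targets, 9 rose, none fell and 5 did not pass, against 10 up and 1 down adjusted over the list alone. Plin4 rose by 1.26, Plin2 by 0.95 and Pparg itself, the nuclear receptor of fat storage, by 0.56. The median of that list was 0.77, and the list shifted (camera adjusted p = 2.54e-11, and 0.0399 with an estimated correlation).

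Fatty acid oxidation moved the same way as storage. Among 33 PPAR-alpha targets and fatty acid oxidation genes, 23 rose, none fell and 10 did not pass (26 up and 1 down adjusted over the list alone), with a median of 0.50. Vnn1, a pantetheinase and a sensitive PPAR-alpha target, rose by 1.51, Acadm of mitochondrial oxidation by 0.83 and Cpt1a, the entry enzyme of mitochondrial oxidation, by 0.77. Cyp4a14, a fatty acid hydroxylase gene, rose by 2.85 ± 0.56 (SE). Of 23 tricarboxylic acid (TCA) cycle genes 6 rose and 17 did not pass (12 up adjusted over the list alone), among them Dlst at 0.51 and Idh2 at 0.36. The camera test called both lists, with adjusted p of 1.43e-15 and 1.46e-06. With an estimated correlation neither passed, at adjusted p of 0.0543 for the PPAR-alpha list and 0.314 for the TCA cycle.

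Many drug metabolism and antioxidant genes were higher as well. Of 26 targets of CAR and PXR, the receptors that induce drug metabolism, 14 rose and 12 did not pass (18 up adjusted over the list alone), with a median of 0.43. Cyp2b9, a steroid hydroxylase gene that is also female-biased, rose by 3.25 ± 0.33 (SE) and Aldh1a7, an aldehyde dehydrogenase gene, by 1.05. Of 25 genes of the NRF2 antioxidant response 11 rose, 2 fell and 12 did not pass (18 up and 3 down adjusted over the list alone). Gsta2, a glutathione transferase gene, rose by 2.14 ± 0.34 (SE), Gstm2 by 1.36 and the quinone reductase gene Nqo1 by 0.94, while the male-biased transferase Gstp1 fell by 2.14 ± 0.34 (SE). Camera called both lists (adjusted p = 4.76e-13 and 7.81e-06), and with an estimated correlation the adjusted p were 0.0543 and 0.265.

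Most male-biased hepatocyte genes fell, and some of the female-biased ones rose. Of 15 male-biased genes 12 fell and 3 did not pass (14 down adjusted over the list alone), with a median of -1.08. Slco1a1, an organic anion transporter gene, fell by 3.23 ± 0.23 (SE), the complement gene C8a by 1.36 and the urinary protein gene Mup5 by 1.28. Of 17 female-biased genes 8 rose and 9 did not pass (8 up and 1 down adjusted over the list alone), with a median of 0.20, or 0.105 with slide series as a block. Cyp3a16 rose by 2.00, Cyp3a44 by 1.98 and Cyp2b13 by 1.39. Probes of these cytochrome families are open to cross-hybridisation between paralogs, as are those of the Mup, Gsta, Ifit and Hsd3b families. Cyp3a16, Cyp3a44, Cyp2b13 and Cyp2b9 are also in the CAR and PXR list, and the female-biased Cyp4a14 is also in the PPAR-alpha list. The rises of these lists are therefore partly rises of the same genes. Camera called the male-biased list with an adjusted p of 2.73e-14, or 0.0399 with an estimated correlation. For the female-biased list these values were 1.45e-05 and 0.0543.

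Most interferon-response genes were higher and most ribosomal protein genes lower. Of 27 interferon-response genes 17 rose and 10 did not pass (21 up adjusted over the list alone), with a median of 0.50. Gbp3, an interferon-induced GTPase gene, rose by 1.28, Ifit3 by 1.12 and Ifit1 by 0.90, and the interferon-inducible Ifi27l2b by 2.19 ± 0.26 (SE). Of 68 ribosomal protein genes 41 fell and 27 did not pass (48 down adjusted over the list alone), with Rps27 at -0.47 and Rps25 at -0.45. Their median of -0.29 changed sign to 0.0706 when arrays were scaled by their median in place of loess. Camera called both lists (adjusted p = 2.14e-14 and 1.58e-24), and with an estimated correlation both had an adjusted p of 0.0543.

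Camera also called the unfolded protein response, 3 sets of cell markers and cholesterol synthesis. Of 21 unfolded protein and integrated stress response genes 2 fell and 19 did not pass (12 down adjusted over the list alone), with Herpud1, of protein degradation at the endoplasmic reticulum, at -1.02. Of 22 hepatocyte markers 4 fell and 18 did not pass (1 up and 8 down adjusted over the list alone), with Ahsg, the fetuin gene, at -0.74, although without high-calorie replicate 4 or 5 its adjusted p was 0.0519 or 0.0618. The median of the hepatocyte markers, -0.22, turned to 0.148 with median scaling, and the list did not pass in that setting, with the Cy3 channel alone or in the deposited scores (adjusted p = 0.136, 0.199 and 0.106). Of 19 stellate cell and fibrosis markers 7 rose, 1 fell and 11 did not pass (7 and 1 adjusted over the list alone), among them the collagen genes Col3a1 at 0.75 and Col1a2 at 0.61. Of 24 Kupffer cell and macrophage markers 1 rose (1 adjusted over the list alone), the cathepsin gene Ctss at 1.08. Of 23 cholesterol synthesis genes 5 rose, 1 fell and 17 did not pass (8 up and 1 down adjusted over the list alone), with Hmgcs1, of the first committed steps, at 1.32 and Msmo1 at 1.09. Camera called these 5 lists with adjusted p of 1.45e-05, 0.00598, 0.00357, 0.00884 and 0.000524 in the order given. With an estimated correlation none passed, at 0.378, 0.212, 0.265, 0.705 and 0.503. The Kupffer cell list had a median of 0.22, which was 0.0530 without background correction (adjusted p = 0.122) and 0.107 with Cy3 brightness as a covariate (0.0884), and within day 1 its adjusted p was 0.317. With median scaling the unfolded protein list was at 0.0792. With brightness as a covariate the cholesterol synthesis median was 0.178, against 0.28, and the NRF2 median was 0.281, against 0.46.

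The remaining largest falls came from several functions. Hsd3b4, a steroid dehydrogenase gene whose probe is open to cross-hybridisation with its paralog Hsd3b5, was at -2.02 ± 0.17 (SE). The growth factor receptor gene Egfr, a member of the male-biased list counted above, was at -1.72 ± 0.29. The kinase gene Ptk2b was at -1.67 ± 0.29, the iron hormone gene Hamp at -1.64 ± 0.17 and the cell adhesion gene Cdh1 at -1.62 ± 0.18. Igf1, the growth factor gene, fell by 0.30 (adjusted p = 0.00956), but was at 0.121 with median scaling. Sirt1, the deacetylase often studied with resveratrol, differed by -0.00054 ± 0.054 (SE) and its partner Ppargc1a by 0.06 ± 0.06 (SE), and neither passed. Srebf1, Fasn, Scd1, Igfbp1, G6pc and Cyp7a1 did not pass in this comparison, at -0.31, -0.25, 0.32, 0.55, 0.27 and 0.16.

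The array images were processed by Feature Extraction on 2 days, and the slide numbers were cut into 2 series at their largest gap. Neither divided evenly among the groups. With extraction day as a block 2515 genes differed between high-calorie and standard-diet mice, and with slide series as a block 1884. Of the genes named for this comparison, Ahsg no longer passed with slide series as a block (adjusted p = 0.0511), and with brightness as a covariate Herpud1, Idh2, Ctss, Msmo1 and Ahsg did not (0.05003, 0.0562, 0.0614, 0.0662 and 0.119). Within day 1 the count was 815, within day 2 it was 55 and within slide series 2 it was 837. Within day 1, day 2 and slide series 2 the male-biased median was -1.19, -1.01 and -1.03, the PPAR-alpha median was 0.46, 0.64 and 0.51, and the interferon median was 0.52, 0.51 and 0.52. The share of higher genes was 56.9%, and 79.0% with median scaling, 80.5% with the Cy3 channel alone and 80.8% in the deposited scores. The count was 2020, 1507, 1761 and 5995 without standard-diet replicate 1, 3, 4 and 5, and 1705, 1759, 1911 and 1379 without high-calorie replicate 1, 2, 4 and 5.

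**Figure D1:**
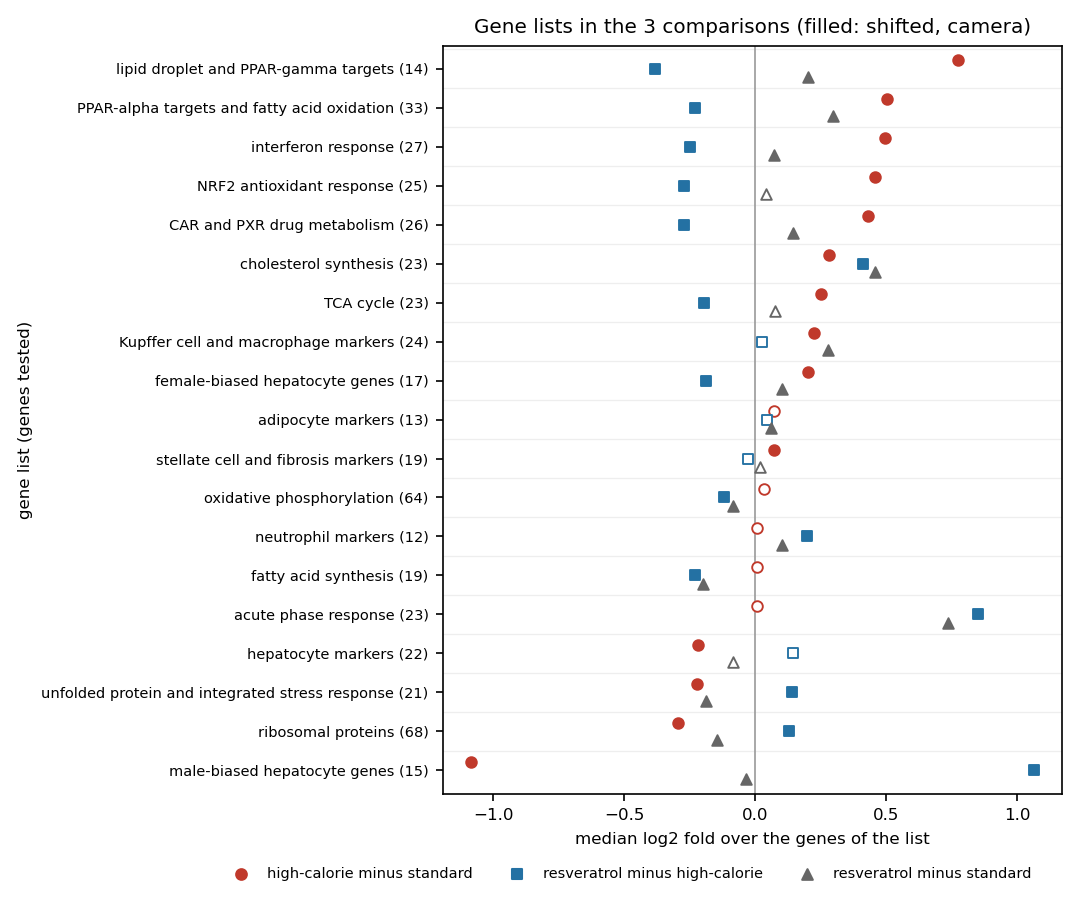
Median log2 fold over the tested genes of each of the lists that shifted in any comparison, with list names and numbers of genes on the vertical axis. Filled markers are lists called by camera with a preset correlation; the male-biased median was -1.08 with the diet and 1.06 when resveratrol was added, and the ribosomal median changed sign in each comparison with median scaling.

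Resveratrol added to the high-calorie diet moved many of the same genes the other way. Some male-biased and cholesterol synthesis genes rose, and some genes of fat storage, drug metabolism, the antioxidant response and the interferon response fell. Camera called 15 of the 35 lists at its preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.106. Hsd3b5 rose the most, by 2.58 ± 0.35 (SE, log2; adjusted p = 0.00398), and the largest fall was in Gsta2, which fell by 2.50 ± 0.36 (SE, log2; adjusted p = 0.00432). Of the 32675 genes 1760 differed between resveratrol and high-calorie mice, 1033 higher and 727 lower, and 51 differed by more than 2-fold.

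Male-biased genes led the rises. Of the 15, 8 rose and 7 did not pass (10 up adjusted over the list alone), with a median of 1.06. Slco1a1 rose by 2.27 ± 0.24 (SE), C8a, a gene of the terminal complement complex, by 1.33 ± 0.22 and Mup5 by 1.24 ± 0.20. C8b, the partner of C8a and not in the list, rose by 1.56 ± 0.22. Of the 17 female-biased genes 4 fell and 13 did not pass (1 up and 6 down adjusted over the list alone). Cyp2b9 fell by 2.44 ± 0.35 (SE) and Cyp2b13 by 1.23, both also in the CAR and PXR list. Cyp2a4 of the female-biased list fell by 1.39 ± 0.30, and the closely related Cyp2a5, which is not in it, by 1.43 ± 0.30. Without resveratrol replicate 1 their adjusted p were 0.0708 and 0.0692. Camera called the male-biased list (adjusted p = 1.49e-12) and the female-biased list (0.00211), and with an estimated correlation neither passed (0.106 and 0.327).

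Some fat storage genes and a few fatty acid oxidation genes fell. Of the 14 lipid droplet and PPAR-gamma genes 6 fell and 8 did not pass (1 up and 8 down adjusted over the list alone), with a median of -0.38. Cd36 fell by 1.37 ± 0.20 (SE), Cidec by 1.17 and Mogat1, of triglyceride synthesis, by 0.47. Of the 33 PPAR-alpha genes 3 fell and 30 did not pass (1 up and 13 down adjusted over the list alone), and Vnn1 was the clearest, at -0.71, although without resveratrol replicate 1 its adjusted p was 0.0571. Of the TCA cycle genes 1 fell (5 down adjusted over the list alone), Idh2 at -0.46. Camera called these lists with adjusted p of 8.55e-06, 9.42e-05 and 0.000165. The PPAR-alpha median of -0.23 was -0.134 without resveratrol replicate 3 (adjusted p = 0.0124). With an estimated correlation none passed, at 0.240, 0.436 and 0.436.

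Drug metabolism, antioxidant and interferon genes fell in part. Of the 26 CAR and PXR targets 5 fell and 21 did not pass (12 down adjusted over the list alone), among them Cyp2b10 at -0.43. Of the 25 NRF2 genes 9 fell and 16 did not pass (11 down adjusted over the list alone), with Gstm2 at -1.20 and Nqo1 at -0.73. Of the 27 interferon-response genes 11 fell and 16 did not pass (1 up and 15 down adjusted over the list alone), with Ifit3 at -0.88, Ifit1 at -0.79 and Ifi27l2b at -1.62 ± 0.28 (SE). Camera called these 3 lists with adjusted p of 8.55e-06, 8.55e-06 and 5.07e-10, and with an estimated correlation none passed, at 0.327, 0.342 and 0.296.

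Some cholesterol synthesis genes rose with the diet, and some rose with resveratrol on top of it. Of the 23 genes 9 rose and 14 did not pass (12 up adjusted over the list alone), with a median of 0.41 (camera adjusted p = 6.39e-08, and 0.342 with an estimated correlation). Hsd17b7 rose by 0.73 and Ebp by 0.43, both of the later steps of the pathway. Msmo1 rose by 1.08, with an adjusted p of 0.0512 without high-calorie replicate 1 and 0.0658 without resveratrol replicate 3. Of the 68 ribosomal protein genes 16 rose and 52 did not pass (24 up and 1 down adjusted over the list alone), with Rps21 at 0.44, but their median of 0.13 was -0.0328 with median scaling. Camera called that list with an adjusted p of 4.99e-10, and 0.327 with an estimated correlation. It did not call it with median scaling, with the Cy3 channel alone or in the deposited scores, at 0.213, 0.926 and 0.102.

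Inflammation and energy lists were called as well. None of 23 acute phase genes passed over all genes by limma (5 rose adjusted over the list alone, and 7 were higher at an unadjusted p under 0.05), although their median was 0.85 (camera adjusted p = 8.63e-07, and 0.436 with an estimated correlation). That median rested largely on resveratrol replicate 3, without which it was 0.19 (camera adjusted p = 0.00365). Of 64 oxidative phosphorylation genes 2 fell (1 adjusted over the list alone), of 19 fatty acid synthesis genes 1 fell (3 adjusted over the list alone), of 12 neutrophil markers 1 rose (1 adjusted over the list alone), and of the 21 unfolded protein genes 1 rose (2 adjusted over the list alone). Camera called these lists with adjusted p of 8.55e-06, 0.00103, 0.0103 and 0.0291, and with an estimated correlation none passed, at 0.436, 0.442, 0.436 and 0.598. Without resveratrol replicate 3 the oxidative phosphorylation median went from -0.12 to -0.0726 (adjusted p = 0.0297), and the neutrophil and unfolded protein lists no longer passed, at 0.149 and 0.337, and without replicate 4 the unfolded protein list was at 0.158. With median scaling the unfolded protein list was at 0.590 and with slide series as a block at 0.14.

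Other large changes fell mostly outside these lists. Egfr, a member of the male-biased list, rose by 1.82 ± 0.31 (SE). Ttc39c, a gene of little known function, rose by 1.34 ± 0.13, although another Ttc39c probe gave -0.06. Ptk2b rose by 1.29 ± 0.31 (SE), with an adjusted p of 0.0690, 0.0641, 0.0531 and 0.0631 without high-calorie replicate 1, 2, 3 and 5, and 0.0842 without resveratrol replicate 1. Lgals1, a galectin gene of stromal and immune cells, fell by 1.44 ± 0.21 (SE) and the surface antigen gene Ly6d by 1.27 ± 0.20. Cidea was lower on every resveratrol array than on any high-calorie array, but did not pass. Igf1 rose by 0.33 (adjusted p = 0.0146, or 0.0600 without resveratrol replicate 1). Sirt1 was at -0.05 ± 0.06 (SE) and Ppargc1a at -0.11 ± 0.06, and neither passed, nor did Cpt1a at -0.40, Pparg at -0.32, Scd1 at -0.96, Fasn at -0.36, Srebf1 at -0.30, G6pc at -0.18, Igfbp1 at 0.54 or Cyp7a1 at 0.40.

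All resveratrol arrays had their images processed on day 1, with only 2 of the 5 high-calorie arrays. With extraction day as a block 445 genes differed between resveratrol and high-calorie mice, and with slide series as a block 672. Of the genes named for this comparison, Ptk2b, Cyp2a5, Cyp2a4 and Vnn1 no longer passed with either block, at adjusted p of 0.113, 0.0555, 0.0559 and 0.0857 with day and 0.0769, 0.0517, 0.0528 and 0.0527 with series, and Hsd17b7 did not with day (0.0546). Within day 1 the count was 52, and within slide series 1 limma called 0 genes, with 3986 at an unadjusted p under 0.05. Within day 1 and within slide series 1 the male-biased median was 1.25 and 1.29, the cholesterol synthesis median 0.47 and 0.44, and the lipid droplet median -0.41 and -0.42. The share of higher genes was 58.7%, but 25.8% with median scaling, 31.1% with the Cy3 channel alone and 33.3% in the deposited scores, where the counts were 120, 45 and 48. The count was 893, 752, 1120 and 658 without high-calorie replicate 1, 2, 3 and 5, and 352 and 959 without resveratrol replicate 1 and 3.

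**Figure D2:**
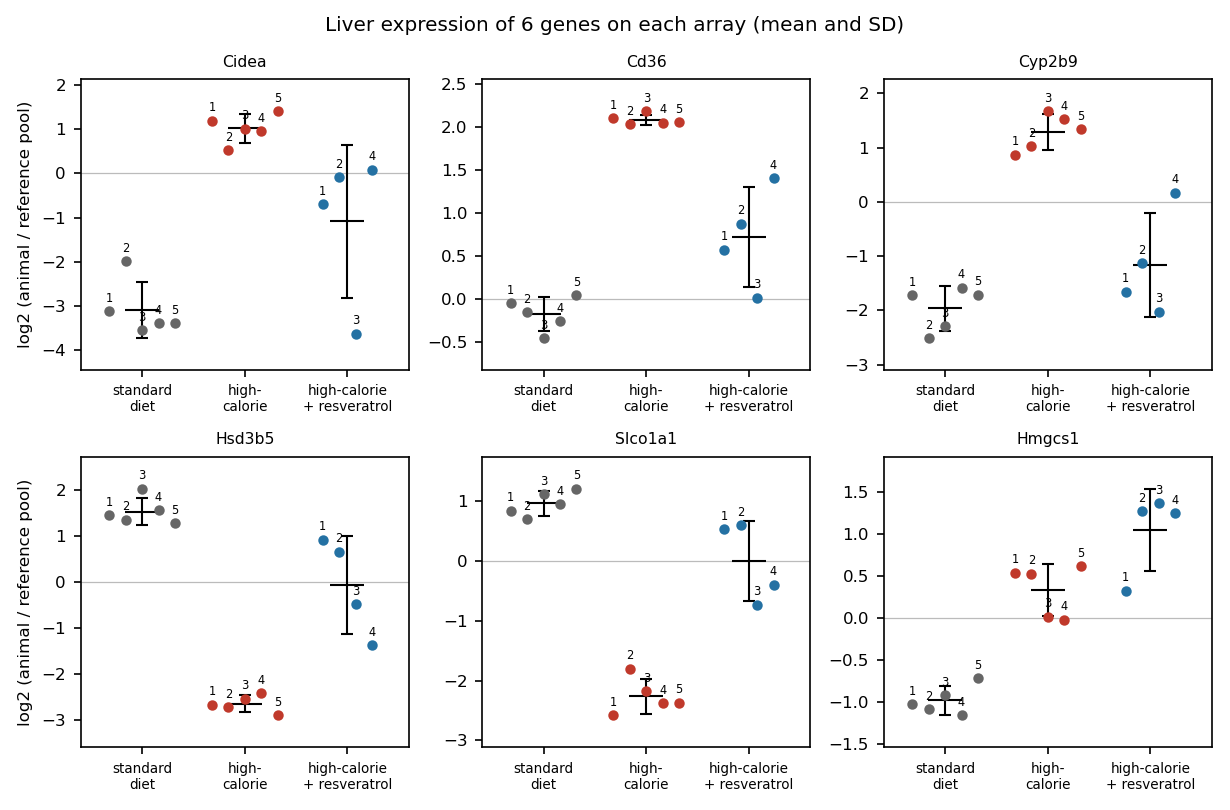
Log2 ratio of animal to reference pool for 6 genes on each array, with points numbered by replicate and bars giving the mean and SD of each group (n = 5, 5 and 4). The mean of Cd36 and of Hsd3b5 in resveratrol mice lay between those of the other groups, Cidea on resveratrol replicate 3 was at -3.64, and Hmgcs1 was highest in 3 of the 4 resveratrol arrays.

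The resveratrol mice differed from standard-diet mice in far fewer genes, and the clearest group among these was cholesterol synthesis. Some fat-related genes stayed higher. Of the 32675 genes 70 differed, 41 higher and 29 lower, and 9 differed by more than 2-fold. That count was 23 to 214 when 1 array was left out. Of 100 splits of the arrays, the real one included, 7 gave at least 70 genes, so chance is not excluded. The count therefore does not measure how far the resveratrol mice returned to the standard-diet state. The largest rises were in Cfd, by 2.57 ± 0.33 (SE, log2; adjusted p = 0.00557), and in Msmo1, by 2.18 ± 0.24 (adjusted p = 0.00244).

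Of the 23 cholesterol synthesis genes 8 rose and 15 did not pass (18 up adjusted over the list alone), with a median of 0.46. Hmgcs1 rose by 2.03 ± 0.20 (SE), Dhcr7, of the last step, by 1.37 ± 0.18 and Hsd17b7 by 1.34 ± 0.16. Idi1 rose by 1.93 ± 0.30 (SE), with an adjusted p of 0.0727 without standard-diet replicate 4 and 0.0655 and 0.0781 without resveratrol replicate 2 and 4. Sqle rose by 1.44 ± 0.25 (SE), with adjusted p between 0.0571 and 0.114 without standard-diet replicate 1, 3 or 4, high-calorie replicate 1 or resveratrol replicate 2 or 4. Camera called the list (adjusted p = 2.56e-25), and with an estimated correlation its adjusted p was 0.0971. The exact permutation of the list mean over all relabellings of the arrays gave the smallest p they allow, 0.00794, and an adjusted p of 0.139.

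Some of the fat-related genes remained higher than on the standard diet. Of the 33 PPAR-alpha genes 2 rose (13 up adjusted over the list alone), among them Acaa1a at 0.63, with adjusted p from 0.0668 to 0.114 without standard-diet replicate 3 or 4 or resveratrol replicate 1, 2 or 4. Of the 14 lipid droplet genes 1 rose (6 up adjusted over the list alone), Plin2 at 0.62, with a list median of 0.20 that was 0.422 without resveratrol replicate 3, and of the 26 CAR and PXR targets 1 rose (7 up adjusted over the list alone), the cytochrome reductase gene Por at 0.87. Of 13 adipocyte markers 1 rose (3 up adjusted over the list alone), which was Cfd. Camera called these 4 lists with adjusted p of 2.28e-14, 2.15e-07, 2.15e-07 and 0.00261, and with an estimated correlation none passed, at 0.122, 0.0971, 0.181 and 0.0971.

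The falls came from several functions. Khk, the fructose kinase gene, fell by 0.80 ± 0.11 (SE). Gpi1, of glycolysis, fell by 0.62 ± 0.10 (SE), Hamp by 1.12 ± 0.18, Cdh1 by 1.01 ± 0.19, the neuritin gene Nrn1 by 0.67 ± 0.11, the cytokine gene Mif by 0.61 ± 0.11 and the ribosome assembly gene Gtpbp4 by 0.50 ± 0.09. The calls of those 6 genes were each lost without standard-diet replicate 3 or 4 or resveratrol replicate 1 or 4, with adjusted p from 0.0578 to 0.139. Some of them were also lost without standard-diet replicate 1, resveratrol replicate 2 or a single high-calorie replicate, with adjusted p from 0.0543 to 0.114. None of the 12 genes named in advance passed here; Sirt1 was at -0.05, Ppargc1a at -0.05, Igf1 at 0.03, Fasn at -0.61, Srebf1 at -0.61, Scd1 at -0.64, Cpt1a at 0.38, Pparg at 0.24, Cyp7a1 at 0.55, G6pc at 0.09 and Igfbp1 at 1.09, and Cyp1a1, above background on 1 array, was not tested in any comparison.

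Male-biased genes showed no call over all genes by limma in this comparison (4 down adjusted over the list alone, and 1 higher and 5 lower at an unadjusted p under 0.05), with a median of -0.03 that was 0.147 with median scaling, 0.03 without resveratrol replicate 4, -0.205 without resveratrol replicate 3 and -0.151 without standard-diet replicate 5. Their camera adjusted p was 0.0477, 0.287, 0.00336 and 0.00172 without these 3 arrays in that order, 0.0841, 0.0633 and 0.386 with day, series or brightness in the model, and 0.553 with an estimated correlation. None of the female-biased or interferon-response genes passed over all genes by limma (4 and 1 up adjusted over the list alone, and 5 and 3 higher at an unadjusted p under 0.05), with camera adjusted p of 0.00261 and 0.00167, and 0.234 and 0.553 with an estimated correlation. The interferon median of 0.07 was 0.0233 without resveratrol replicate 4 (adjusted p = 0.350), 0.0211 with Cy3 brightness as a covariate (0.158) and 0.123 without standard-diet replicate 5, and within day 1 the female-biased list was at 0.101. Of the 68 ribosomal protein genes 2 fell (17 down adjusted over the list alone), with a median of -0.15 that was 0.0249 with median scaling. Their camera adjusted p was 9.25e-16, and 0.144 with an estimated correlation.

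With extraction day as a block 59 genes differed between resveratrol and standard-diet mice, and with slide series as a block 10. With series as a block Dhcr7, Idi1, Sqle, Khk, Acaa1a, Plin2, Gtpbp4, Gpi1, Hamp, Nrn1, Cdh1 and Mif no longer passed, at adjusted p from 0.0836 to 0.337, and Acaa1a did not with day (0.0538). With Cy3 brightness as a covariate Gpi1, Hamp, Sqle, Gtpbp4, Mif and Cdh1 did not, at 0.0786 to 0.121. Within day 1 the count was 55, and the cholesterol synthesis median was 0.52 within day 1 and 0.51 with slide series as a block. The slide series could not be compared within this contrast, since series 1 held no standard-diet array and series 2 held 1 resveratrol array. The share of higher genes was 58.6%, and 80.0% with the scanner's processed signals, 82.4% with median scaling, 88.9% with the Cy3 channel alone and 100% in the deposited scores, where the counts were 30, 17, 9 and 4. The count was 45, 214, 30, 23 and 159 without standard-diet replicate 1 to 5, 42, 44, 42 and 44 without high-calorie replicate 1 to 4, and 41, 210 and 28 without resveratrol replicate 2, 3 and 4.

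Across genes, the change with resveratrol opposed the change with the diet. Because both changes share the high-calorie arrays, those arrays were divided between the 2 differences, and the median correlation over the 20 divisions was -0.602, with a range of -0.662 to -0.567. This correlation is across 32245 genes, which are not independent replicates. A two-sided exact permutation over all relabellings of the high-calorie and resveratrol arrays gave p = 0.00794, the smallest they allow, and the other relabellings gave -0.522 to 0.414. With day or slide series as a block it was -0.583 and -0.611, and within day 1 it was -0.450, where an exact permutation gave p = 0.0667, the smallest possible there.

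Among called genes, 1040 changed in opposite directions with the diet and with resveratrol, and 4 changed in the same direction, but both calls use the same high-calorie arrays, which by itself favours opposite changes. Independent calls of these numbers would give 81.1 opposite pairs, a value that leaves out the shared arrays, and 20 simulations with shared arrays gave at most 0, a value that leaves out the effects, so the excess over either does not measure a shared effect. When these arrays were divided, fewer arrays entered each comparison, and a median of 511 genes was called with the diet and 14 with resveratrol. A median of 6 genes was then called in opposite directions (0 to 53), against 0.121 expected for independent calls, and 0 in the same direction. In these divisions a median of 95.5% of the genes called with the diet moved back with resveratrol (90.1% to 98.4%), by a median of 0.32 against a diet change of 0.56. The plot of single genes shows Cd36, Slco1a1, Hsd3b5 and Cyp2b9 moving back. Hmgcs1 did not pass between resveratrol and high-calorie mice, and resveratrol replicate 1 at 0.32 lay within the high-calorie range of -0.02 to 0.61. In the same divisions a median of 32 of the 35 lists had means that moved in opposite directions (exact permutation p = 0.00794, the smallest possible), and the other relabellings gave at most 30.

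**Figure D3:**
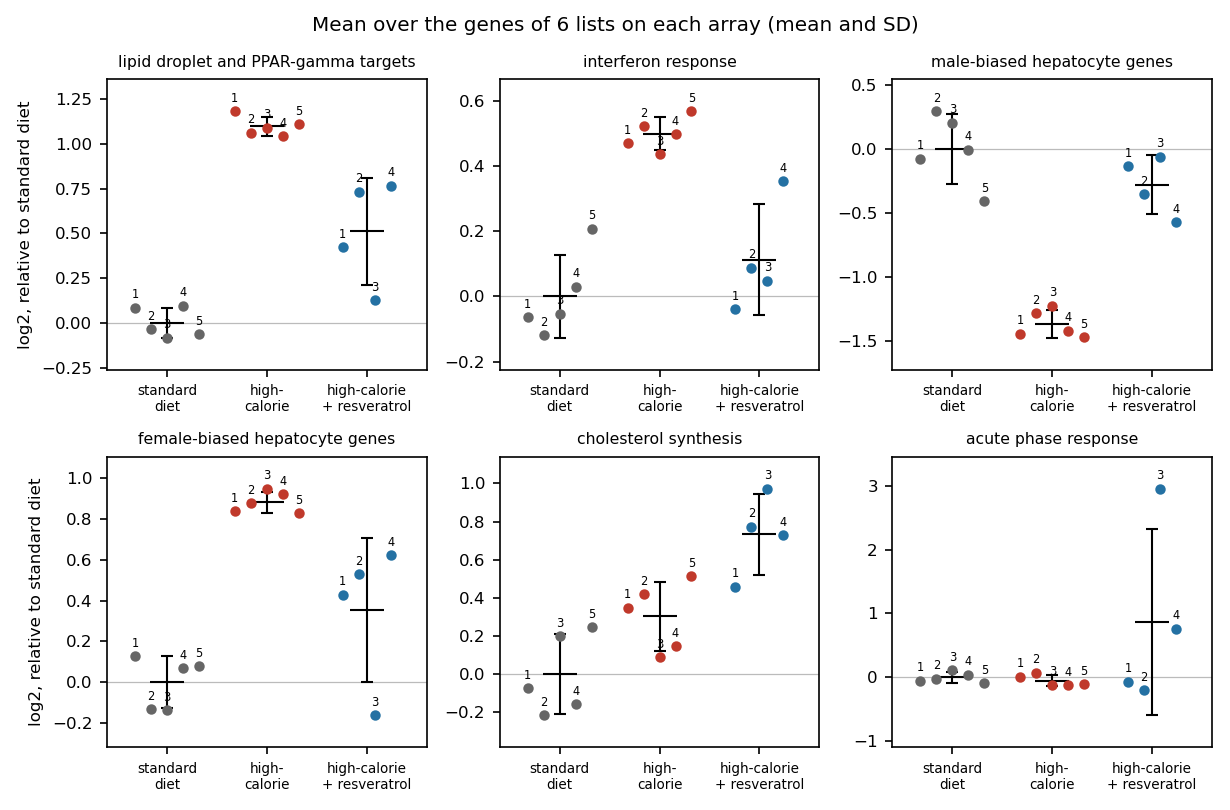
Mean log2 ratio over the tested genes of 6 lists on each array, relative to the standard-diet mean, with points numbered by replicate and bars giving mean and SD (n = 5, 5 and 4). Male-biased genes lay at -1.47 to -1.22 on the high-calorie arrays and at -0.57 to -0.06 on the resveratrol arrays, and the acute phase mean of resveratrol replicate 3 was 2.95.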

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

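The tests of Xist, of the share of hepatocyte RNA, of array quality, of erythroid markers and of a wrong label on resveratrol replicate 3 were chosen after the results they concern had been seen. A gene or list mean was singled out when 1 array lay far from the others of its group, which chance does in about 1 of 20 groups, and 8 of 201 groups met this.

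The opposition between the resveratrol and diet effects was weighed first. The high-calorie arrays were the brightest on average, and the days and slide series were unevenly spread, so each was put into the model. The split correlation was then -0.583 with Cy3 brightness, -0.611 with slide series and -0.583 with extraction day. The permutation p was 0.00794 each time, the smallest possible, but it is not exact here. Each term was removed with the real groups in the model, and the labels were then permuted without refitting it. The correlations argue against brightness, series or day alone as the whole cause. An effect of resveratrol that returns part of the diet response may explain the pattern as a hypothesis. Combinations of these factors were not tested.

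The second pattern was the fall of male-biased and rise of female-biased genes on the high-calorie diet. The highest Xist log2 ratio was 0.19 on a high-calorie array and 0.12 on a standard-diet array, which argues against RNA of female animals, in which this transcript is abundant. A lower share of hepatocyte RNA would lower both sets of genes, unless the diet also induced some of them. The lowest high-calorie array exceeded the highest standard-diet array by 0.70 in the mean over female-biased genes. That mean, 0.88 over the high-calorie arrays, rests on a few strong rises, as the median of the list was 0.20, so it cannot decide this. The hepatocyte markers themselves were lower on the high-calorie arrays, with means of -0.41 to -0.12, while the male-biased means were -1.47 to -1.22. A lower hepatocyte share therefore stays open as a small part of the fall of male-biased genes, and the values of the hepatocyte markers argue against it as the whole cause. With brightness in the model the male-biased mean still differed by -1.25 ± 0.14 (SE), against -1.37 without it. A response of hepatocytes to the diet may explain this, as a hypothesis found and tested on the same data.

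The third pattern was resveratrol replicate 3, whose acute phase mean of 2.95 compared with -0.06, -0.20 and 0.76 on the other resveratrol arrays. It lay outside the range of the other arrays in 0 of 4 quality measures, and its erythroid mean of -0.20 was near the standard-diet range of -0.19 to 0.30, which argues against a poor array and against blood left in the tissue. Over 210 genes that the other resveratrol arrays changed against standard diet, it moved their way by 0.14. Each standard-diet array was left out in turn with the genes chosen anew (89 to 514 genes), which gave -0.10 to 0.24. Standard-diet replicates 2 and 5 lay above 0.14, at 0.20 and 0.24 over 490 and 514 genes. The other resveratrol arrays, left out likewise, gave 0.38, 0.54 and 0.56. These gene sets differ, so the values are not strictly comparable, and a standard-diet animal under a wrong label stays open. In a first form of that test, with the standard-diet arrays inside the choice of genes, the highest of them was 0.08, and the test was revised after that was seen. Its cholesterol synthesis mean of 0.97, against at most 0.25 on standard-diet arrays, and its Cfd ratio of -0.13, against at most -1.64, point the other way, and acute inflammation in this mouse may be another explanation that was not tested.

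Cidea was at -1.98 on standard-diet replicate 2 and at -3.55 to -3.13 on the other standard-diet arrays. Cyp7a1, the bile acid synthesis gene, was at 0.0783 on standard-diet replicate 1 and at -0.80 to -0.63 on the others. Hmgcs1 was at 0.32 on resveratrol replicate 1 and at 1.25 to 1.37 on the others. Khk was at 0.29 on resveratrol replicate 2 and at -0.17 to -0.11 on the others. Mup5 was at 1.26 on resveratrol replicate 1 and at 0.62 to 0.70 on the others, and Ttc39c on the same array was at 0.68 against 0.15 to 0.21. The TCA cycle mean was -0.41 on standard-diet replicate 2 and 0.04 to 0.20 on the others. The mean over stellate cell and fibrosis markers was 0.0858 on high-calorie replicate 5 and 0.13 to 0.14 on the others.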

How the results depend on the processing

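The smaller offset, the blocks and subsets by extraction day and slide series, the brightness covariate, the joint omission of standard-diet replicate 5 and resveratrol replicate 3, and the exact permutation of list means were chosen after seeing the data. Counts within 1.5 times the reported one came from 12 of 21 settings for high-calorie against standard diet (2514 to 3552 genes), 8 of 20 for resveratrol against high-calorie (1274 to 2494) and 9 of 19 for resveratrol against standard diet (48 to 73).

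In that order of comparisons, the counts were 430, 45 and 9 genes with the Cy3 channel alone, 442, 48 and 4 in the deposited scores, 7023, 3059 and 167 with array weights, and 1884, 672 and 10 with slide series as a block. High-calorie against standard diet gave 859 genes with brightness as a covariate, 6673 without standard-diet replicate 5 and resveratrol replicate 3, 815 within day 1, 55 within day 2 and 837 within slide series 2. Resveratrol against high-calorie gave 2695 without background correction, 685 with processed signals, 120 with median scaling, 951 with an offset of 10, 445 with day as a block, 52 within day 1 and 0 by limma within slide series 1 (3986 at an unadjusted p under 0.05). Resveratrol against standard diet gave 32 without background correction, 30 with processed signals, 17 with median scaling, 24 from the arrays of these groups alone, 31 with brightness and 514 without the 2 arrays named. Subsets hold fewer arrays; the cause of the other moves was not tested. Without any filter on dim probes the counts were 2859, 1613 and 65.

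The lists numbered 14, 15 and 15, and 13 to 18, 14 to 19 and 11 to 16 in 23 of 24, 20 of 23 and 19 of 22 settings. With an estimated correlation camera called 2, 0 and 0, with the lowest adjusted p at 0.0399, 0.106 and 0.0971. Fry called 15, 8 and 5 lists and the exact permutation 16, 9 and 0. The sign of a list's median and of its camera test differed for 5, 0 and 2 lists. The opposition was -0.450 within day 1 (exact permutation p = 0.0667, the smallest possible there) and -0.825 to -0.333 in 19 of 20 settings. Those 19 include the correlation with undivided arrays, -0.730, which is negative by construction and averaged -0.470 in simulations with no effect. They also include the correlation over genes called with the diet, which had no permutation test.

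Leaving out 1 array at a time gave 1379 to 5995, 352 to 2573 and 23 to 214 genes, 14 to 15, 14 to 19 and 12 to 18 lists, and an opposition of -0.631 to -0.557. The replicate numbers were not taken to pair the animals, since deviations correlated above 0.1 in 4 of 13 same-numbered pairs and not in all. As a hint the other way, 7 of 14 arrays had the one with their own number as the best-correlated array of another group. With the replicate number as a block the counts were 2883, 407 and 48 genes and 14, 16 and 14 lists, and the opposition was -0.591. Quantile normalisation of average intensities leaves log ratios as they are by construction.

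Of 188 passing values of named genes, 122 passed in every fit that left out 1 array, and 67 under every alternative planned in advance other than leaving out arrays. No longer passing were 50 with slide series as a block, 34 with extraction day, 48 with brightness, 67 with median scaling, 109 with the Cy3 channel alone and 112 in the deposited scores, and in the order of comparisons slide series ended 17, 18 and 15 calls, day 8, 23 and 3, and brightness 36, 3 and 9. With high-calorie against standard diet, median scaling reversed Igf1 (0.121), Per2 (0.0169), Pecam1 (-0.0338), Apoc3 (0.136) and Hnf4a (0.00231). Hnf4a was at 0.123 with the Cy3 channel alone and 0.0505 in the deposited scores. With resveratrol against high-calorie, Myc was at 0.0409 and 0.0246 in those settings. The cause was not tested. Dim probes limit what could be seen, and 3421 genes were removed by the filter.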

Other observations

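The tests of growth hormone signalling and of other splits were written down before their results were seen. The exact permutation of list means, the blocks and subsets by day or slide series, the brightness covariate, and the remarks on ratios to the reference pool and on single genes were chosen after seeing the data.

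Genes of lists that did not shift also changed with the high-calorie diet. Some of them are also in shifted lists, such as Cyp7b1 and Slco1a1 in the male-biased list. Nqo1 of the AhR targets is also in the NRF2 list. Among 19 genes of bile acid and cholesterol export 3 rose and 3 fell (3 and 3 adjusted over the list alone): the phospholipid transporter gene Abcb4 rose by 0.83 and the anion transporter gene Slco1a4 by 0.76, while Cyp7b1, of the alternative bile acid route, fell by 1.06. With resveratrol on that diet these moved back, Abcb4 at -0.61, Slco1a4 at -0.63 and Cyp7b1 at 1.21. Of 14 genes of the IGF axis 1 rose and 2 fell (3 and 2 adjusted over the list alone), with the binding protein gene Igfbp2 at -1.54 and Stat5a at 0.57. Of 15 gluconeogenesis and insulin signalling genes 1 rose and 2 fell (2 and 3 adjusted over the list alone), with the glucose-6-phosphate transporter Slc37a4 at -0.50. Of 17 glycolysis genes 1 rose and 1 fell (2 and 2 adjusted over the list alone), with Hk2, a hexokinase low in normal hepatocytes, at 0.93, and it fell by 0.62 with resveratrol. Of 15 heat shock protein genes 2 rose and 3 fell (2 and 3 adjusted over the list alone), with the mitochondrial Hspd1 at 0.35 (adjusted p = 0.0734 with Cy3 brightness as a covariate) and the cytosolic Hspa8 at -0.88.

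Of 23 sirtuin, AMPK and mitochondrial biogenesis genes 3 rose with the diet (5 up and 2 down adjusted over the list alone), led by the NAD synthesis gene Nampt at 0.71, and none passed with resveratrol by limma (0 adjusted over the list alone, and 5 at an unadjusted p under 0.05), where Nampt was at -0.46 with an adjusted p of 0.0661. Of 18 immediate early genes 1 rose with the diet, Klf6 at 0.52 (1 adjusted over the list alone), and it fell by 0.38 with resveratrol. With the diet, of 24 cell cycle genes 3 rose (5 and 2 adjusted over the list alone), of 18 liver endothelial markers 2 rose (2), of 15 cholangiocyte markers 2 rose (2 and 1), of 18 T, NK and B cell markers 1 rose and 1 fell (1 and 1), of 7 AhR targets 2 rose and 1 fell (2 and 2), and of 17 circadian clock genes 1 fell (2 and 1). Among 30 proteasome genes, 6 erythroid and 11 exocrine pancreas markers limma called 0 with the diet (0 adjusted over the list alone), with 10, 2 and 2 at an unadjusted p under 0.05. Camera called none of these 16 lists in any comparison, and its lowest adjusted p for them was 0.0698. With the diet fry called 2 of them, the sirtuin list (0.0412) and the immediate early genes (0.0479), as did the exact permutation (0.0185 each). Of the lists called only in other comparisons, with the diet 3 of 64 oxidative phosphorylation genes and 4 of 19 fatty acid synthesis genes rose (3 and 4 adjusted over the list alone), 1 of 23 acute phase genes fell (1) and no neutrophil marker passed by limma (0 adjusted over the list alone, and 2 at an unadjusted p under 0.05). Camera did not call adipocyte markers with the diet (adjusted p = 0.422; 3 up and 1 down of 13, 3 and 2 adjusted over the list alone), but fry did (0.0412) and so did the exact permutation of the list mean (0.0185), and Fabp4 was at 1.60 on 1 probe and -0.12 on another.

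In resveratrol against standard-diet mice camera called 6 more lists. Kupffer cell markers (median 0.28, adjusted p = 2.15e-07) and the unfolded protein response (-0.19, 0.00232) were called with no single gene past by limma, also adjusted over the list alone, as were fatty acid synthesis (-0.20, 0.00936) and neutrophil markers (0.10, 0.0233). At an unadjusted p under 0.05 these 4 lists had 7, 4, 4 and 1 genes. Acute phase genes had a median of 0.74 (adjusted p = 7.31e-06), which was 0.115 without resveratrol replicate 3 and 0.313 with slide series as a block, with 1 gene past, Hamp, which fell (1 adjusted over the list alone). Oxidative phosphorylation had a median of -0.08 (adjusted p = 3.14e-05), which was -0.00679 without resveratrol replicate 3, with 0 genes past by limma (2 down adjusted over the list alone, and 18 at an unadjusted p under 0.05), and 0.0860 with median scaling. With an estimated correlation none of the 6 passed, at 0.482, 0.553, 0.557, 0.553, 0.553 and 0.553. The Kupffer cell mean was 0.57 and 0.86 on resveratrol replicates 3 and 4, but -0.10 and 0.01 on replicates 1 and 2, inside the standard-diet range of -0.16 to 0.09, and the median of that list was 0.127 with slide series as a block and 0.109 without resveratrol replicate 4. With slide series as a block the acute phase, fatty acid synthesis, oxidative phosphorylation and neutrophil lists had adjusted p of 0.0783, 0.243, 0.0540 and 0.397. Within day 1 the unfolded protein list had a median of -0.0975 and an adjusted p of 0.151. Without resveratrol replicate 3 the acute phase, fatty acid synthesis, oxidative phosphorylation and neutrophil lists were at 0.307, 0.181, 0.281 and 0.466, with medians of -0.119 and 0.0433 for fatty acid synthesis and neutrophil markers, and without standard-diet replicate 5 the fatty acid synthesis and neutrophil lists were at 0.218 and 0.151.

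In the 5 standard-diet livers the log2 ratio to the pool of standard-diet livers averaged -3.09 ± 0.64 (SD) for Cidea and -2.05 ± 0.24 (SD) for Cfd, and every standard-diet array was below 0 for both. Without a dye swap, more of these transcripts in the pool and a dye effect of the probes cannot be told apart.

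Lower growth hormone signalling through STAT5 might lower male-biased genes, raise female-biased ones and lower Igf1, and it was tested on Igf1, Igfals, Socs2, Cish and Ghr. Only 1 of these 5 genes, Igf1, passed as lower on the high-calorie diet. Socs2 was at -0.69 ± 0.40 (SE) and Cish at -0.77 ± 0.53 (SE), Igfals at -0.02 and Ghr at -0.05, none past the threshold, so the prediction was not met.

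Other splits of the arrays into groups of the same sizes asked whether chance could give as many calls, with 100 splits per comparison, the real one included. For high-calorie against standard diet 1 split gave at least 3084 genes, the real one, and the highest other gave 255. Ranking first of 100 splits argues against chance for that count, but does not exclude it. The gap between these counts does not measure the effect, since mixing arrays of groups that differ widens the spread and lowers adjusted calls. At an unadjusted p under 0.05 the highest other gave 8640 against 9027 in the real split. For resveratrol against high-calorie 1 split gave at least 1760 genes, the real one, and the highest other gave 0 by limma. At an unadjusted p under 0.05 the other splits gave at most 5520, against 7245 in the real split. The real split again ranked first, which argues against chance without excluding it. For resveratrol against standard diet 7 splits gave at least 70 genes and the highest other gave 708, so chance is not excluded, and a split with that many calls points to a structure of the arrays, whose nature was not tested. For the lists, 12, 21 and 21 splits gave at least the real 14, 15 and 15. The highest others gave 16, 21 and 20, so chance is not excluded for the number of lists called. With the diet, each other split with at least 14 lists exchanged only 1 array between the groups. Such splits keep most of the real contrast, so for the diet this count cannot tell chance from a kept difference. The split by extraction day gave 0 genes by limma (2545 at an unadjusted p under 0.05) and 2 lists for high-calorie against standard diet, and the split by slide series 0 genes (1599 unadjusted) and 14 lists for resveratrol against high-calorie. Those 14 lists are nearly as many as the real 15; with slide series as a block 15 lists were called.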
